A study of Mus musculus with 9 samples.

How the data were processed

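Single-cell transcript counts of 9 livers were used, 1 per mouse, with 3 mice each for PBS, AAVrh.10Null and AAVrh.10mCherry, grouped by the treatment given in the labels. Per the labels' protocols, cells were captured by Drop-seq and sequenced on a HiSeq 2500 with 101 cycles, and the deposited readme names bcl2fastq 2.19. Per the submitters' processing notes, reads were assigned to the mouse genome mm10 and the analysis was made with Seurat, with no version given. The aligner, the counting tool, the annotation and the threshold that chose the barcodes were not given in the sources used here. The deposited files hold a count of UMIs per gene and barcode, as whole numbers without scaling, in 1 table per mouse with 3600 to 7200 barcodes. Each label describes a separate mouse, and replicate numbers are not shared between groups. A feature named mCherry is listed in 6 of the 9 files and was taken as 0 in the others.

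Barcodes with at least 200 genes and at most 50% mitochondrial UMIs were retained, and genes seen in at least 3 retained barcodes were kept for clustering. The filter removed 3051 of the 3600 barcodes of mouse 7, of which 3050 had under 200 genes, 202 of mouse 6, of which 197 were over the mitochondrial limit, and at most 15 of any other mouse. The depth per mouse was 11220152, 5669210, 5931278, 5332360, 4234216, 5062265, 1083091, 6729394 and 8585145 UMIs for mice 1 to 9, and the median per retained barcode was 386 (mouse 7) to 1990 (mouse 1) UMIs. Levels of single features over the retained barcodes of a mouse are given with exact 95% Poisson intervals, and 0 UMIs are set against a floor of 3 UMIs. At these totals that floor was 10.3 CPM at the thinnest point for mCherry in mouse 7. In mice 2 and 8, 7 and 20 of 7200 barcodes ended in an undetermined base. Mouse 7 (PBS) had 174 of 3600, and the other mice had 1056 to 1735 of 4000 to 6400. This is a sign of a processing batch, and Malat1 was also highest in mice 2, 7 and 8. A batch of mice 2 and 8 would hold AAVrh.10Null mice only, and whether mouse 7 belongs to it could not be told. AAVrh.10mCherry minus PBS lies within the other 7 mice, with mouse 7 on the PBS side. AAVrh.10Null is mouse 5 alone among them, too few for a test, with Igkv3-12 at 248 CPM.

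Clustering used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Counts were scaled to 10000 per barcode and log-transformed, 2000 variable genes were chosen within mice, and 30 principal components, 15 neighbours and Leiden resolution 1.0 were used on all mice together with no batch integration. Clusters were named by marker lists chosen before the data were examined. The cluster with non-parenchymal markers was clustered again with 20 components at resolution 1.0. This second step, a profile correlation of at least 0.9 with other hepatocyte-like clusters, a 4-fold rule for marker clusters and a 2-fold rule for clusters led by nuclear RNA were chosen after the data had been seen. A pseudocount of 50 CPM was used in the folds of cluster genes. Of 12 clusters, 7 were hepatocyte-like, 1 non-parenchymal, 3 led by haemoglobin or mixed RNA and 1 below the correlation limit; the last 4 were left unnamed and enter only the sums over all barcodes. Shares of single mice in the hepatocyte-like clusters reached 55.2% (mouse 1), 55.3% and 69.8% (mouse 9), 85.6% (mouse 8) and 99.7% (mouse 6). Scrublet marked 37 of 44709 barcodes, too few to be usable, so doublets were not removed and the alternative without them was not run.

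UMIs were summed per mouse and class, a mouse entering a class with at least 20 barcodes and a contrast needing at least 2 mice per group. This left hepatocyte-like sums (123083 to 10835416 UMIs), endothelial-like sums (9287 to 104601 UMIs, without mouse 5) and sums over all retained barcodes (290531 to 11220147 UMIs). The other classes had too few barcodes for a gene test. In R 4.3.3, edgeR 4.0.16 was used with TMM normalization, filterByExpr and quasi-likelihood tests on all 9 mice in 1 fit, with group as the only term. The contrasts were AAVrh.10Null minus PBS, AAVrh.10mCherry minus PBS, the mean of both minus PBS, and AAVrh.10mCherry minus AAVrh.10Null, with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. The biological coefficient of variation was 0.274 for hepatocyte-like, 0.324 for endothelial-like and 0.266 for all-barcode sums. Fold changes are log2, and levels of genes in sums are TMM-normalised CPM as mean ± SD of the mice.

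Named genes followed a rule set before the data were examined: the largest changes among passing genes, and where fewer than 3 passed, the 3 per direction with the smallest p, given as not passing, and mCherry throughout. Up to 4 members with the smallest p were taken for each passing list. Igkv3-12, AI480526 and Snhg20 in the sums over all barcodes, and the genes of mouse 6, were chosen after their values had been seen. The 37 gene lists, also set before the data were examined, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, wherever at least 3 members were measured. The tests were repeated with the correlation estimated per list and with fry, whose p asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. With an estimated correlation and with fry, 0 lists passed in each class and contrast. The complement list was shifted 2-fold in sums simulated with genes drawn independently of each other. With an estimated correlation it was recovered over all barcodes (adjusted p = 0.000417 and 0.000418 in the contrasts of AAVrh.10Null and AAVrh.10mCherry with PBS). It was also recovered in hepatocyte-like sums (0.00152 and 0.00194) and, for AAVrh.10mCherry only, in endothelial-like sums (0.071 and 0.00539). Independent genes make the estimated correlation small by construction. So this does not show what the test could find in the real sums, where genes may move together.

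Gene tests were also tested on simulated data, with 200 genes changed in sums drawn at the mean levels, depths and spread of the 9 mice. Genes were drawn independently, so structure common to many genes was not simulated. At a 4-fold change 84.5% and 83.7% were recovered in hepatocyte-like sums, 67.8% and 80.5% in endothelial-like sums, and 81.8% and 84% over all barcodes (AAVrh.10Null and AAVrh.10mCherry). At a 2-fold change 18.2% and 15.3%, 5.6% and 18.2%, and 19.6% and 12.1% were recovered. Unchanged genes called numbered 10 and 10, 6 and 0, and 3 and 7. Shares of cell classes were compared by an exact two-sided permutation test of the difference of means, 16 tests in all. The correlation and covariance of the contrasts with PBS were set against 20 simulated sets of unchanged groups. In each set all 9 mice were redrawn, with genes independent of each other, and both contrasts shared the redrawn PBS mice. The 3 PBS mice could not be divided into parts of at least 2, so a version with separate controls was not made.

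Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, its Wald test, limma-voom, no filter on low counts, at least 10 counts in at least 6 mice, and only the mice of the groups compared. Further ones were at least 100 or 500 genes per barcode, at most 20% mitochondrial UMIs, Leiden resolution 0.5 and sums thinned to the smallest total. Others were endothelial-like sums without 50 genes taken to lead the free RNA, each mouse left out in turn, an overlap threshold of 0.1, another denominator and an edgeR test for the shares. Those 50 genes were the ones with the most UMIs over all retained barcodes, and free RNA itself was not measured. Added after the data had been seen were leaving out mice 6 and 7, adding the 3 haemoglobin-led or all 4 unnamed clusters to the hepatocyte-like sums, leaving out the nuclear-led clusters, and leaving out the endothelial-like sub-cluster from mouse 6. Group labels were also exchanged among the mice in every possible way, and each contrast was fitted again. This gave 84 splits for 6 mice against 3, 56 in endothelial-like sums without mouse 5, and 10 for 3 against 3. For both AAV groups against PBS these fits merged the AAV mice into 1 group, unlike the main fit.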

Results

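Liver cells of 9 male C57BL/6 mice aged 8 weeks were profiled by Drop-seq, which captures single cells with barcoded beads in droplets and counts transcripts as unique molecular identifiers (UMIs). The mice had received PBS, AAVrh.10Null or AAVrh.10mCherry into a vein, with n = 3 mice per group, and AAVrh.10 is an adeno-associated virus serotype used to carry genes to the liver. The vector dose and the time from injection to collection were not given in the sources used here. Of 48000 barcodes, 44709 were retained, and 20393 genes were seen in at least 3 of them. Most named barcodes were hepatocyte-like (143 to 6859 per mouse). Much smaller classes were endothelial-like (17 to 121 per mouse), T/NK-like (2 to 73), Kupffer/macrophage-like (2 to 35), stellate/fibroblast-like (2 to 15), B-like (0 to 15) and cholangiocyte-like (0 to 7).

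The libraries differed before any comparison. Mouse 7 (PBS) held 1083091 UMIs and 549 retained barcodes of 3600, and its median correlation with the other mice was 0.807 against 0.927 to 0.959 for the other mice. Malat1, a nuclear long RNA, was at 23010 CPM (UMI counts scaled to a common total per mouse) in mouse 2 (AAVrh.10Null), 15020 in mouse 8 (AAVrh.10Null) and 15980 in mouse 7, and at 2769 to 10040 in the other 6 mice. Clusters led by nuclear RNA made up 28.5 ± 4.01% of the retained barcodes of the AAVrh.10Null mice, 11.2 ± 3.89% of the PBS mice and 15 ± 6.24% of the AAVrh.10mCherry mice (mean ± SD, n = 3). Unnamed clusters led by haemoglobin or mixed RNA took 48.7 ± 40.7% of the PBS, 26.1 ± 32.0% of the AAVrh.10Null and 0.260 ± 0.294% of the AAVrh.10mCherry barcodes. Their profiles correlated at 0.992, 0.987 and 0.921 with the largest hepatocyte-like cluster. Together with the hepatocyte-like barcodes they are called hepatocyte-dominated below. Without them the hepatocyte-like sums hold 946 of 4798 retained barcodes of mouse 4, 2512 of 7195 of mouse 2 and 143 of 549 of mouse 7. The hepatocyte-like clusters followed single mice as well: 1 was 99.7% from mouse 6 and another 85.6% from mouse 8, and mCherry and Igkv3-12 were among the genes that led them. Sums over all retained barcodes of a mouse, which do not depend on the clusters but mix expression with cell composition, are therefore given first, with hepatocyte-like and endothelial-like sums beside them.

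**Figure D1:**
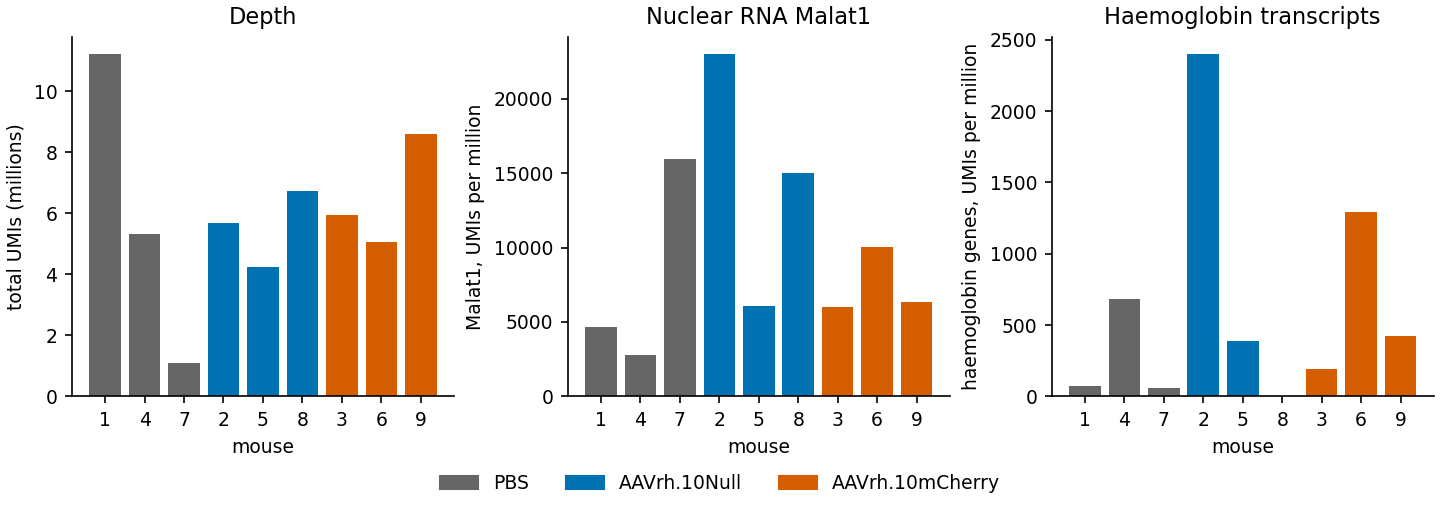
Total UMIs, Malat1 CPM and haemoglobin CPM in each of the 9 mice, with 1 bar per mouse coloured by group. Total UMIs ran from 1083091 in mouse 7 to 11220152 in mouse 1, and Malat1 was highest in mice 2, 7 and 8.

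mCherry, the red fluorescent protein carried by 1 of the vectors, marked the group that its label names. In the AAVrh.10mCherry mice it reached 7979 (95% Poisson interval 7907 to 8051), 6364 (6293 to 6435) and 1797 (1769 to 1826) CPM in mice 3, 6 and 9. It was found in 99.9%, 97.6% and 86.4% of their retained barcodes. Free RNA may add to this, so the share of cells making mCherry is not known. T/NK-like barcodes held mCherry in 100%, 82.8% and 85.7%, with Alb at 64.8%, 36.9% and 73.4% of the hepatocyte-dominated level. Among the other mice, mouse 1 (PBS) held 24.3 (21.5 to 27.4) and mouse 5 (AAVrh.10Null) 22.7 (18.4 to 27.7), mouse 8 held 1 UMI, and mice 2, 4 and 7 held 0. Pooled over the mice of a group, the level was 298-fold that of PBS and 828-fold that of AAVrh.10Null, where all 273 PBS UMIs came from mouse 1 and 96 of the 97 AAVrh.10Null UMIs from mouse 5. Another feature separated the groups in the opposite sense: Igkv3-12, a variable segment of the immunoglobulin kappa light chain locus, was at 124 (115 to 134), 248 (233 to 263) and 232 (220 to 244) CPM in AAVrh.10Null mice 2, 5 and 8. It was at 3.12 (1.75 to 5.14) in mouse 6 and at 0 UMIs in the other 5 mice.

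**Figure D2:**
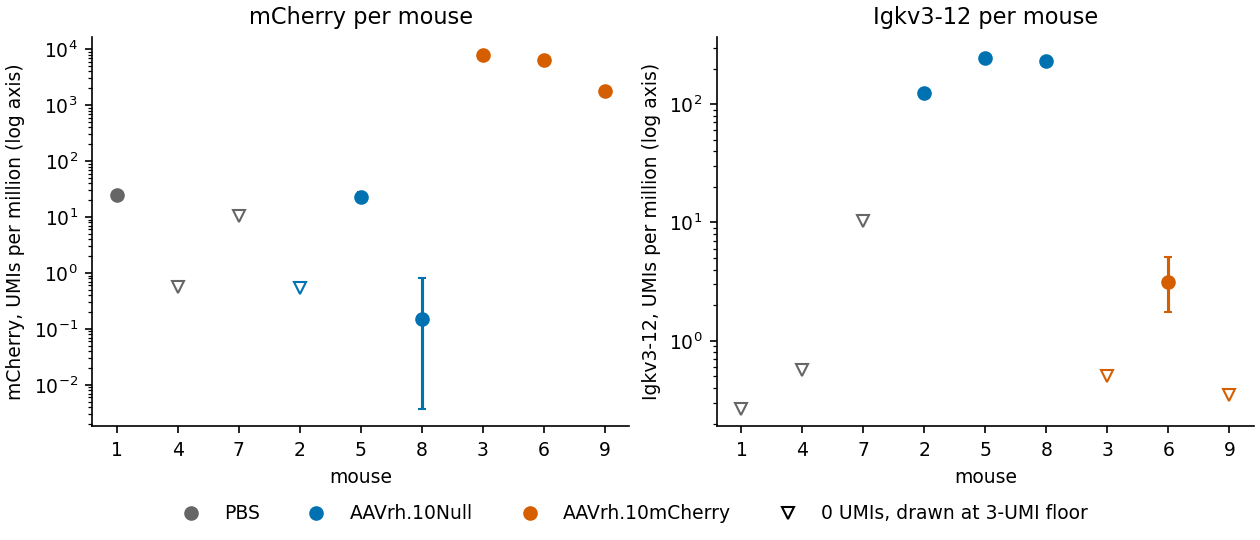
mCherry and Igkv3-12 CPM per mouse on a log axis, with 95% Poisson intervals and open triangles for mice with 0 UMIs, drawn at the level that 3 UMIs would give. mCherry lies between 1797 and 7979 in the AAVrh.10mCherry mice, and Igkv3-12 between 124 and 248 in the AAVrh.10Null mice.

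AAVrh.10Null against PBS came first. A possible batch of mice 2 and 8 is mixed with treatment in each contrast with AAVrh.10Null. In the sums over all barcodes, Igkv3-12 rose in the AAVrh.10Null mice (log2 change 13.25, SE 1.49, adjusted p = 0.0343, n = 3 per group). Pooled over the mice of a group, the level was 1118-fold a PBS floor of 3 UMIs. Mouse 1 gave 11220147 of the 16843037 PBS UMIs behind that floor. Igkv3-12 was the only gene of 11308 to pass, and it passed in 13 of the 18 settings that tested it. Exchanged group labels gave at least the 5 lists found here in 10 of 10 splits, so their number does not stand out. For both AAV groups 69 of 84 did, for AAVrh.10mCherry 7 of 10 against PBS and 2 of 10 against AAVrh.10Null. Of the ribosomal protein genes 61 of 61 were lower (median log2 change −0.47, adjusted p = 4.18e-10). So were 51 of 52 nuclear genes of oxidative phosphorylation, which builds ATP in mitochondria (median −0.32, adjusted p = 3.27e-09). MHC class II genes let antigen-presenting cells show peptides to T cells. They fell in 9 of 9 (median −1.28, adjusted p = 0.00346, 3 lower when adjusted over the list alone). NRF2 antioxidant and metallothionein genes fell in 16 of 19 (median −0.29, adjusted p = 0.00527). Transcripts encoded by the mitochondrial genome rose in 10 of 10 (median 0.88, adjusted p = 0.000477). Each of the 5 lists had adjusted p = 0.833 with an estimated correlation, and no single member passed over all genes. Mitochondrial transcripts made up 11.4 ± 5.11% of the UMIs of the AAVrh.10Null mice, 6.64 ± 2.96% of those of the PBS mice and 10.7 ± 4.75% of those of the AAVrh.10mCherry mice. The nuclear-led barcodes given above were also most frequent in the AAVrh.10Null group. Without mouse 4 the MHC class II list had adjusted p = 0.529, and without mouse 2 the NRF2 list had 0.0569. Mouse 4 (PBS) also held the largest shares of T/NK-like (1.52%), Kupffer/macrophage-like (0.729%) and B-like barcodes (0.313%). By edgeR 1460 genes had an unadjusted p under 0.05, where 565 would be expected, DESeq2 called 59 genes and limma-voom 0.

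In the hepatocyte-like sums, Igkv3-12 was again the only gene of 10293 to pass (log2 change 12.87, SE 1.59, adjusted p = 0.0123, 204 ± 97.3 against 0 CPM). The genes with the next smallest p did not pass (adjusted p = 0.586 for each). Ugt1a6a, which conjugates phenols with glucuronic acid, was at 33.2 ± 3.39 against 14.1 ± 2.51 (log2 change 1.37). Snhg15, a snoRNA host RNA, was at 6.71 ± 2.68 against 0.967 ± 0.872 (2.34), and Cyp2c69, a cytochrome P450, at 2.56 ± 1.94 against 18.7 ± 11.6 (−2.28). Ccdc12 had −0.98, and Isg15, an interferon-induced ubiquitin-like protein, had −1.37 (SE 0.40). Of 36 lists, 6 fell. In hepatocyte-like sums, genes of endothelial and immune cells may come from free RNA or mixed barcodes, which was not tested. Ribosomal proteins (58 of 61, median −0.20, adjusted p = 0.000886, examples Rpl13a −0.61 and Rps23 −0.52) and oxidative phosphorylation (47 of 52, −0.16, 0.00098, Sdhd −0.57) had adjusted p = 0.734 with an estimated correlation. Apolipoproteins (16 of 17, −0.27, adjusted p = 0.00719, Apoc1 −0.36 and Apoa2 −0.37), MHC class II (6 of 7, −0.97, 0.00748, Cd74 −1 at 7.38 ± 1.49 against 13.5 ± 6.28) and endothelial identity genes (10 of 13, −0.31, 0.0121) had adjusted p = 0.674 with an estimated correlation. Acute phase genes (20 of 25, −0.23, adjusted p = 0.0123, Fga −0.55 at 1590 ± 286 against 2320 ± 490) had adjusted p = 0.534 with an estimated correlation. Each of the 6 was lost without a single mouse: without mouse 2 ribosomal proteins (adjusted p = 0.498) and oxidative phosphorylation (0.24), and without mouse 4 MHC class II (0.114), acute phase (0.0935), apolipoproteins (0.092) and endothelial identity (0.092). Without the clusters led by nuclear RNA none of the 6 passed, with adjusted p = 0.288 to 0.956, and the direction of MHC class II, apolipoprotein and oxidative phosphorylation genes turned upward. DESeq2 and limma-voom called 0 genes here, while edgeR called 462 with at most 20% mitochondrial UMIs and 61 with no filter on low counts. By edgeR 818 had an unadjusted p under 0.05, and Igkv3-12 passed in 16 of the 22 settings that tested it.

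Type I interferon genes, induced when cells sense viral nucleic acid, did not pass in any class or contrast (lowest adjusted p = 0.115). Over all barcodes 25 of 32 were below 0 in AAVrh.10Null against PBS (median −0.25, adjusted p = 0.24), and examples in hepatocyte-like sums lay on either side of 0: Mx2 0.93, Stat2 0.80, Oasl1 −0.89. Lists of innate nucleic acid sensing (lowest adjusted p = 0.413), NF-kB targets (0.0652), macrophage activation (0.115) and AAV receptors and trafficking (0.531) passed nowhere either. The same held for periportal zonation (0.115), urea cycle and amino acid catabolism (0.0681), and gluconeogenesis and glycolysis (0.247). In simulated sums over all barcodes, for AAVrh.10Null minus PBS, 81.8% of genes changed 4-fold and 19.6% of those changed 2-fold were called. Genes were drawn independently there, without the structure of the real libraries, so these values give no power for real genes or lists. mCherry, 298-fold PBS when pooled, had adjusted p = 0.722 against PBS over all barcodes.

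Endothelial-like sums compared 2 AAVrh.10Null mice with 3 PBS mice, since mouse 5 held 17 such barcodes. Mitochondrially encoded transcripts rose in 9 of 9 members (median 1.28, adjusted p = 2.01e-06, mt-Cytb 9570 ± 1630 against 3740 ± 739) and had adjusted p = 0.532 with an estimated correlation. Fibrosis and stellate genes, which lay down and remodel matrix, rose in 7 of 7 (median 0.79, adjusted p = 0.000556, Mmp14 378 ± 6.36 against 192 ± 161, Timp3 0.93, Dcn 1.55) and had adjusted p = 0.401 with an estimated correlation. Endothelial identity genes rose in 13 of 14 (0.45, adjusted p = 0.0159, Stab1 0.76; 0.787 with an estimated correlation). Cytochrome P450 genes fell in 13 of 17 (−0.38, 0.0159, Cyp2e1 −1), apolipoproteins in 11 of 12 (−0.39, 0.038) and pericentral genes in 9 of 12 (−0.33, 0.038). Cholesterol genes fell with 2 of 4 below 0 (−0.68, adjusted p = 0.0386, Sc5d −1.42), and these 4 lists had adjusted p = 0.787 with an estimated correlation. NRF2 genes (11 of 13 lower, −0.39, adjusted p = 0.0308, Ftl1 −1.80 at 669 ± 343 against 2410 ± 1120) and lipogenesis genes (6 of 6 lower, −0.62, 0.038) fell too, with adjusted p = 0.401 with an estimated correlation. Alb, a marker of free hepatocyte RNA, had a log2 change of −0.10 (SE 0.56), and Cyp2e1 was also among the genes that lead the free RNA. The endothelial-like barcodes lay in sub-clusters of unequal origin, and 35.5% of the sub-cluster led by Timp3 and Mmp14 came from mouse 2. Fibrosis genes alone kept their call without each mouse. Mitochondrial transcripts were lost without mouse 8 (adjusted p = 0.0602), endothelial identity without mouse 1 (0.28), and P450 (highest 0.375), apolipoprotein (0.846) and pericentral genes (0.908) without any 1 of mice 1, 4 and 8. By edgeR 0 of 1509 genes passed and 45 had an unadjusted p under 0.05, where 75 would be expected. DESeq2 and limma-voom called 0. Lgals1, a galactose-binding lectin, was at 965 ± 118 against 213 ± 91.7 (log2 change 2.02, SE 0.50, adjusted p = 0.715). Cdk11b, a kinase of transcription and splicing, was at 483 ± 106 against 73.3 ± 71.5 (2.21, 0.715), and Ddx46, a splicing helicase, at 1.75.

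AAVrh.10mCherry against PBS came next. Over all barcodes mCherry had a log2 change of 8.74, yet its adjusted p was 0.722 in the all-gene test, with 24.3 CPM in 1 PBS mouse and 0 in the others. Nuclear oxidative phosphorylation genes fell in 52 of 52 (median −0.34, adjusted p = 2.24e-10), immunoglobulin genes in 6 of 6 (−2.46, 0.000106, 6 lower when adjusted over the list alone), apolipoproteins in 16 of 17 (−0.28, 0.000118), lipogenesis genes in 15 of 20 (−0.37, 0.00266) and acute phase genes in 20 of 26 (−0.19, 0.00981). These 5 had adjusted p = 0.443 with an estimated correlation. Mouse 7 (PBS) held Igkc at 382, Igha at 213 and Jchain at 68.8 CPM, against at most 20.6, 0.938 and 1.31 in the other mice. Male-biased growth hormone targets (26 of 30, −0.63, adjusted p = 7.19e-07), complement (23 of 27, −0.36, 0.000316) and MHC class II genes (9 of 9, −1.01, 0.000474) fell, with adjusted p = 0.705 with an estimated correlation. Coagulation (19 of 24, −0.20, adjusted p = 0.00415; 0.699 with an estimated correlation) and MHC class I genes (20 of 21, −0.36, 0.000152; 0.589 with an estimated correlation) fell as well. So did cholesterol synthesis (18 of 25, −0.22, adjusted p = 0.00348), ribosomal (58 of 61, −0.25, 0.000378) and cell cycle genes (16 of 18, −0.29, 0.0438), while heat shock genes, which refold proteins, rose in 21 of 32 (0.13, 0.00981). These 4 had adjusted p = 0.719 with an estimated correlation, and heat shock genes turned downward without mouse 4 (adjusted p = 0.408). Only oxidative phosphorylation, male-biased, immunoglobulin and apolipoprotein genes kept their call without each mouse in turn, with the male-biased list at adjusted p = 0.0443 without mouse 6. By edgeR 0 of 11308 genes passed and 731 had an unadjusted p under 0.05, DESeq2 called 2 genes and limma-voom 0.

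Among 10293 genes of the hepatocyte-like sums, mCherry was at 5680 ± 3460 against 8.98 ± 15.6 CPM (log2 change 8.60, SE 1.44, adjusted p = 0.202). Male-biased genes, which follow pulsed growth hormone, fell in 25 of 30 (median −0.67, adjusted p = 1.28e-08, Mup19 −1.23, Cyp4a12b −1.58, Igfals −0.66). They had adjusted p = 0.596 with an estimated correlation, and adjusted p = 0.12 without mouse 6 but 1.6e-05 without mice 6 and 7. Complement fell in 24 of 27 (−0.29, adjusted p = 7.31e-06), with C4b at 201 ± 53.1 against 470 ± 249 and C1ra at 86.3 ± 14.9 against 130 ± 13.2. This list had adjusted p = 0.572 with an estimated correlation. Coagulation fell in 19 of 22 (−0.29, adjusted p = 7.31e-06), with prothrombin F2 at 764 ± 63.3 against 1150 ± 120 and protein C (Proc) at 293 ± 44.1 against 508 ± 161. It had adjusted p = 0.31 with an estimated correlation. Lipogenesis fell in 17 of 20 (−0.29, adjusted p = 0.000191, Acly 74.2 ± 5.33 against 114 ± 8.70, Acss2 −0.89, Acacb −1.23; adjusted p = 0.31 with an estimated correlation). Cholesterol synthesis fell in 17 of 25 (−0.24, 0.00671, Dhcr7 28.1 ± 7.84 against 56.2 ± 14.4; 0.836 with an estimated correlation). Acute phase genes fell in 20 of 25 (−0.22, adjusted p = 0.00701, Hpx −0.79, Hamp 0.70) and immunoglobulin genes in 3 of 3 (−1.59, 3.37e-05, Igkc 1.76 ± 0.727 against 9.22 ± 13.4, 3 lower when adjusted over the list alone). Each had adjusted p = 0.263 with an estimated correlation.

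More hepatocyte-like lists of this comparison passed. MHC class II fell in 6 of 7 (median −0.58, adjusted p = 0.00282, H2-Ab1 −1.15) and apolipoproteins in 13 of 17 (−0.20, 0.0108, Pltp −1.37), each with adjusted p = 0.572 with an estimated correlation. MHC class I fell in 16 of 20 (−0.31, adjusted p = 0.0108, H2-K1 658 ± 84.5 against 959 ± 291, H2-T23 −0.95) and had adjusted p = 0.836 with an estimated correlation. Ribosomal protein genes rose in 59 of 61 (0.27, adjusted p = 0.000567, Rpl14 0.50), opposite to their fall over all barcodes. They had adjusted p = 0.84 with an estimated correlation, and without mouse 6 they turned downward (adjusted p = 0.551). Without mouse 1 lipogenesis (adjusted p = 0.191) and cholesterol synthesis (0.631) did not pass, without mouse 9 acute phase (0.149), MHC class II (0.0945) and apolipoproteins (0.164), and without mouse 4 MHC class I (0.309). Without the clusters led by nuclear RNA acute phase (adjusted p = 0.0787), MHC class II (0.168) and ribosomal genes (0.53) did not pass. By edgeR 0 genes passed and 314 had an unadjusted p under 0.05, where 515 would be expected, and DESeq2 and limma-voom called 0. Genes with the smallest p besides mCherry had an adjusted p of 1. They were Pawr, a pro-apoptotic regulator (8.66 ± 1.40 against 4.17 ± 3.29), Pla2g12a, a secreted phospholipase (23.4 ± 13.1 against 6.58 ± 2.04), the lysosomal transporter Slc46a3 (15.4 ± 3.47 against 30.3 ± 5.68), the pseudogene Mup-ps20 (−1.81) and Dct (−1.43).

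In the endothelial-like sums of the same mice, mCherry was the only gene of 1509 to pass, at 4040 ± 2720 against 6.80 ± 11.8 CPM (log2 change 8.26, SE 0.89, adjusted p = 1.78e-05, n = 3 per group). The ratio of mCherry to Alb transcripts in these barcodes was 1.01, 1.05 and 1.21 times that of hepatocyte-dominated barcodes in the 3 mice, and free hepatocyte RNA would give a ratio near 1. Male-biased genes, which are made by hepatocytes, fell in 15 of 17 (median −1.03, adjusted p = 3.27e-09, Mup17 −1.35, Elovl3 167 ± 149 against 588 ± 105) and lipogenesis genes in 6 of 6 (−1, 0.000254, Thrsp −1.18, Agpat2 −1.41), with adjusted p = 0.557 and 0.195 with an estimated correlation. Complement (13 of 16, −0.30, adjusted p = 0.0137; 0.711 with an estimated correlation) and oxidative phosphorylation genes (39 of 50, −0.24, 0.0137, Cox5a −0.78; 0.658 with an estimated correlation) also fell. Endothelial identity genes rose in 12 of 14 (0.45, adjusted p = 0.0275, Pecam1 0.68, Bmp2 0.67; 0.711 with an estimated correlation) and mitochondrially encoded transcripts in 9 of 9 (0.57, 0.00754, mt-Rnr1 1.21; 0.677 with an estimated correlation). Endothelial activation genes rose in 7 of 7 (0.41, adjusted p = 0.0311) and heat shock genes in 9 of 13 (0.48, 0.0327, Hspa8 0.65), each with adjusted p = 0.557 with an estimated correlation. Msr1, a scavenger receptor (563 ± 302 against 165 ± 40.1), the chaperonin subunit Cct8 (1.84), the bile acid enzyme Cyp8b1 (−1.93) and Osgin1 (−1.61) did not pass (adjusted p = 0.905). Each of the 8 lists was lost without at least 1 mouse: without mouse 6 male-biased (adjusted p = 0.2, but 0.000781 without mice 6 and 7), oxidative phosphorylation (0.2) and complement genes (0.92), without mouse 9 lipogenesis (0.0944) and mitochondrial transcripts (0.301), and without mouse 1 identity (0.549), activation (0.653) and heat shock genes (0.28). An endothelial-like sub-cluster came to 98% from mouse 6, and without it 2 lists passed in place of 8.

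Both AAV groups together were compared with PBS, with n = 6 and 3. Over all barcodes, oxidative phosphorylation genes fell in 52 of 52 (median −0.32, adjusted p = 1.38e-11), MHC class II in 9 of 9 (−1.15, 0.000537, 5 lower when adjusted over the list alone) and MHC class I in 19 of 21 (−0.32, 0.00181). Immunoglobulin genes, high in mouse 7 as given above, fell in 6 of 6 (−1.60, adjusted p = 0.0028, 3 lower when adjusted over the list alone). Apolipoproteins fell in 15 of 17 (−0.23, 0.00247). NRF2 genes fell in 16 of 19 (−0.26, adjusted p = 0.03) and mitochondrially encoded transcripts rose in 10 of 10 (0.58, 0.00141). Each list so far had adjusted p = 0.645 with an estimated correlation. The share of mitochondrial UMIs was higher in either AAV group than in PBS, as given above. Ribosomal genes fell in 61 of 61 (−0.34, adjusted p = 2.32e-08; 0.811 with an estimated correlation) and cholesterol genes in 17 of 25 (−0.16, 0.0269; 0.834 with an estimated correlation). Without mouse 4 the lists for MHC class II (adjusted p = 0.59), MHC class I (0.37), immunoglobulin (0.137), apolipoproteins (0.0981), NRF2 (0.0927), mitochondrial transcripts (0.0706) and ribosomal proteins (0.0981) did not pass, and oxidative phosphorylation alone kept its call without each mouse. By edgeR 0 genes passed over all barcodes with 1212 at an unadjusted p under 0.05, 0 in hepatocyte-like sums with 313, and 0 in endothelial-like sums with 46. DESeq2 called 7, 0 and 0 genes and limma-voom 0, 0 and 0.

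In hepatocyte-like sums of both AAV groups 10 lists fell, and without the clusters led by nuclear RNA none of them passed (adjusted p = 0.0945 to 0.772). Coagulation fell in 19 of 22 (median −0.23, adjusted p = 0.000898, Proc −0.53) and apolipoproteins in 15 of 17 (−0.25, 0.000902). MHC class II fell in 6 of 7 (−0.79, 0.000898, Cd74 −0.79, H2-Ab1 −1.07). So did immunoglobulin genes in 3 of 3 (−1.12, 0.003, 1 lower when adjusted over the list alone). Lipogenesis fell in 14 of 20 (−0.28, 0.0113, Elovl5 102 ± 37.6 against 184 ± 8.80). These lists had adjusted p = 0.485 with an estimated correlation. Acute phase genes fell in 20 of 25 (−0.20, adjusted p = 0.001; 0.183 with an estimated correlation), complement in 20 of 27 (−0.15, 0.00529; 0.74 with an estimated correlation) and MHC class I in 16 of 20 (−0.20, 0.0152; 0.74 with an estimated correlation). Cholesterol synthesis fell in 17 of 25 (−0.20, adjusted p = 0.00966, Dhcr7 34.6 ± 10.1 against 56.2 ± 14.4; 0.786 with an estimated correlation) and male-biased genes in 23 of 30 (−0.23, 0.015; 0.811 with an estimated correlation). Coagulation, apolipoproteins and acute phase kept their call without each mouse. Lost were male-biased genes without mouse 6 (adjusted p = 0.965), cholesterol synthesis (0.702) and lipogenesis (0.677) without mouse 1, and MHC class I (0.492), complement (0.278), immunoglobulin (0.133) and MHC class II (0.0749) without mouse 4. Single genes with the smallest p had an adjusted p of 1: Pawr 8.69 ± 1.82 against 4.17 ± 3.29, Snhg15 2.06, choline kinase Chka 73.5 ± 30.8 against 309 ± 347, Slc46a3 −0.85, AC122326.1 −2.08 and Igkv3-12 8.90. The transgene mCherry had a log2 change of 3.87 (adjusted p = 1).

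In endothelial-like sums of both AAV groups (n = 5 and 3), mitochondrially encoded transcripts rose in 9 of 9 (median 0.95, adjusted p = 5.99e-06, mt-Rnr1 1.04; 0.57 with an estimated correlation) and fibrosis and stellate genes in 7 of 7 (0.61, 0.0028, Timp3 0.78, Vim 0.81; 0.332 with an estimated correlation). Endothelial identity genes rose in 13 of 14 (0.37, adjusted p = 0.00396) and activation genes in 6 of 7 (0.24, 0.0344), with adjusted p = 0.712 with an estimated correlation. Male-biased genes fell in 14 of 17 (−0.40, 0.000318), cytochrome P450 genes in 15 of 17 (−0.32, 0.00691), apolipoproteins in 11 of 12 (−0.32, 0.024), phase II conjugation genes in 12 of 14 (−0.31, 0.0317, Gstp1 −0.90) and cholesterol genes in 3 of 4 (−0.54, 0.049), also with adjusted p = 0.712 with an estimated correlation. Lipogenesis fell in 6 of 6 (−0.83, adjusted p = 0.00056, Elovl3 173 ± 107 against 588 ± 105, Fads1 −1.49; 0.256 with an estimated correlation), NRF2 genes in 11 of 13 (−0.29, 0.0245, Ftl1 −1.35; 0.332 with an estimated correlation) and complement in 12 of 16 (−0.17, 0.0344; 0.756 with an estimated correlation). Only mitochondrial and fibrosis genes kept their call without each mouse. Male-biased genes had adjusted p = 0.2 without mouse 6, P450 genes 0.483 and endothelial identity 0.37 without mouse 1, and lipogenesis 0.0589 without mouse 9, and activation genes turned downward without mouse 1 (0.92). Cdk11b (1.75), the nucleic acid-binding protein Purb (1.86) and Dap (−1.42) did not pass (adjusted p = 0.976).

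AAVrh.10mCherry against AAVrh.10Null compared the vectors, with the same possible batch. Over all barcodes 3 genes fell in the AAVrh.10mCherry mice: Igkv3-12 (log2 change −8.02, SE 0.89, adjusted p = 0.0308), and the long non-coding RNAs AI480526 (−1.88, SE 0.25, 0.0346) and Snhg20 (−1.77, SE 0.26, 0.0492). AI480526 was at 13.5, 13.6 and 18.0 CPM in the AAVrh.10Null mice and at 3.395 to 6.93 in the other 6, and Snhg20 at 31.1, 20.04 and 34.4 against 6.69 to 10.4. Barcodes of clusters led by nuclear RNA made up 25.5% to 33.1% in the AAVrh.10Null mice and at most 22.1% in the others, and in hepatocyte-like sums without these clusters Snhg20 had a log2 change of −1.07 in place of −2.55. mCherry had a log2 change of 9.42 and did not pass (adjusted p = 0.527). Male-biased genes fell in 29 of 30 (median −0.98, adjusted p = 1.51e-09) and complement in 24 of 27 (−0.48, 1.06e-05, 2 lower when adjusted over the list alone), and heat shock genes rose in 30 of 32 (0.54, 2.65e-05), each with adjusted p = 0.633 with an estimated correlation. Interferon gamma and guanylate-binding protein genes, a defence against intracellular microbes, rose in 15 of 17 (0.54, adjusted p = 0.00142; 0.682 with an estimated correlation). These 4 lists kept their call without each mouse in turn, with the male-biased list at 0.00191 without mouse 6. In that list mouse 6 stood at a median log2 difference of −3.22 from the PBS mean and mice 3 and 9 at 0.04 and −0.20, against −0.19, 0.50 and 0.67 in the AAVrh.10Null mice. AI480526 passed in 5 of the 19 settings that tested it and Snhg20 in 4 of 19, DESeq2 and limma-voom called 0 genes over all barcodes, though DESeq2 gave no adjusted p for 10304 of the 11308 genes (smallest 0.0508), and 850 genes had an unadjusted p under 0.05.

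Another 13 lists passed over all barcodes in this comparison, and each was lost without at least 1 mouse. Ribosomal (55 of 61 higher, median 0.24, adjusted p = 0.000125) and pericentral genes (17 of 23, 0.27, 0.0499) rose, with adjusted p = 0.717 with an estimated correlation. Endothelial identity (15 of 16, 0.55, adjusted p = 0.0032) and T and NK cytotoxicity genes (8 of 8, 1.10, 0.0221) rose, while immunoglobulin (6 of 6, −1.09, 0.0197), unfolded protein response (21 of 28, −0.21, 0.0372) and bile acid genes (14 of 21, −0.18, 0.0499) fell, all with adjusted p = 0.682 with an estimated correlation. NRF2 (17 of 19, 0.26, adjusted p = 0.0197), p53 and DNA damage (21 of 29, 0.15, 0.034) and apoptosis genes (19 of 22, 0.15, 0.0499) rose, and coagulation (18 of 24, −0.30, 0.00323) and lipogenesis genes (16 of 20, −0.16, 0.0197) fell, with adjusted p = 0.633 with an estimated correlation. Mitochondrially encoded transcripts fell in 8 of 10 (−0.53, adjusted p = 0.034; 0.703 with an estimated correlation). Endothelial-like barcodes made up 1.36% against 0.856% and T/NK-like barcodes 0.405% against 0.204% of the retained barcodes of these groups, the same direction as their lists.

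In hepatocyte-like sums mCherry rose (log2 change 9.46, SE 1.45, adjusted p = 0.0364, 5680 ± 3460 against 8.07 ± 13.8 CPM) and Igkv3-12 fell (−7.95, SE 0.89, 0.00404, 1.11 ± 1.92 against 204 ± 97.3). Male-biased genes fell in 28 of 30 (median −0.95, adjusted p = 6.28e-07). The oxysterol hydroxylase Cyp7b1 was at 137 ± 104 against 426 ± 205 and the pheromone carrier Mup9 at 112 ± 63.4 against 368 ± 204. Complement (19 of 27, −0.37, adjusted p = 0.0196, C2 33.1 ± 10.4 against 80 ± 34.5) and immunoglobulin genes (3 of 3, −0.96, 0.0326) fell. Ribosomal (61 of 61, 0.46, adjusted p = 2.87e-09, Rps23 0.85) and oxidative phosphorylation genes (51 of 52, 0.25, 1.33e-05) rose. So did endothelial identity, perhaps as free RNA (12 of 13, 0.65, 0.000285, Bmp2 1.25, Stab2 0.95, 2 higher when adjusted over the list alone). Heat shock genes rose too (23 of 30, 0.34, 0.00321, Dnajb1 52.2 ± 27.5 against 17.1 ± 4.53, Hsph1 0.98). NRF2 genes rose in 15 of 18 (0.40, adjusted p = 0.00353, Mt2 53.5 ± 38.8 against 8.27 ± 6.67, Gpx4 1.06). Fatty acid oxidation genes rose in 22 of 30 (0.29, 0.0249, Cd36 18.8 ± 7.70 against 7.03 ± 3.48, Acadm 0.84). Each list so far had adjusted p = 0.618 with an estimated correlation. Pericentral genes rose in 17 of 23 (0.41, adjusted p = 0.049, Cyp2c37 317 ± 259 against 90.2 ± 38.5, Cyp2c29 2860 ± 782 against 1240 ± 648; 0.698 with an estimated correlation). Without the clusters led by nuclear RNA, oxidative phosphorylation turned downward (adjusted p = 0.0697) and ribosomal (0.277), NRF2 (0.146), fatty acid oxidation (0.77) and pericentral genes (0.407) did not pass, whereas male-biased (2.38e-12), heat shock (1.25e-06) and complement genes (1.19e-06) passed. Without a single mouse complement (adjusted p = 0.296 without mouse 6), heat shock (0.0534 without mouse 9), NRF2 (0.0971 without mouse 2), fatty acid oxidation (0.0778 without mouse 2), immunoglobulin (0.186 without mouse 8) and pericentral genes (0.446 without mouse 8) did not pass. Genes that did not pass included Hamp2, a relative of the iron hormone hepcidin (249 ± 249 against 30.6 ± 8.35, adjusted p = 0.176), Ugt3a1 (log2 change 2.06, 0.176), AI480526 (3.63 ± 1.37 against 19.2 ± 3.98, 0.0973) and Snhg20 (6.79 ± 3.66 against 41.6 ± 22.7, 0.176). DESeq2 called 6 genes and limma-voom 1, and mCherry passed in 12 of the 23 settings that tested it.

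In endothelial-like sums (n = 3 and 2) mCherry was at 0 in the AAVrh.10Null mice and was the only gene to pass (log2 change 10.50, SE 1.20, adjusted p = 4.44e-05). Male-biased genes fell in 14 of 17 (median −0.95, adjusted p = 7.8e-09, Mup17 −1.90, Mup11 −2.06) and heat shock genes rose in 11 of 13 (0.58, 0.01, Hspa8 1.08, Jun 0.94), each with adjusted p = 0.89 with an estimated correlation. Lgals1 was at 277 ± 164 against 965 ± 118 (adjusted p = 0.314), and Mef2a (log2 change 1.83), Hspa4 (1.81), Mup9 (−2.35) and Mup18 (−2.73) did not pass. Without mouse 6 the male-biased list had adjusted p = 0.556, and without mouse 9 heat shock genes had 0.293.

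The male-biased list was lowest in mouse 6, at a median log2 difference of −3.22 from the PBS mean, against −0.67 to 0.67 elsewhere. Genes with higher expression in female livers were high in mouse 6: Cyp2b9 was at 238 CPM (at most 3.44 elsewhere), Sult2a7 at 52.2 (at most 3.44) and Cyp2b13 at 17.3 (0 elsewhere). Mup20, a male pheromone, was at 1101 against 3717 to 17902 in the other mice, while Ddx3y of the Y chromosome was at 104, within the range of 59.7 to 126 of the others. These genes were chosen after their values had been seen.

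**Figure D3:**
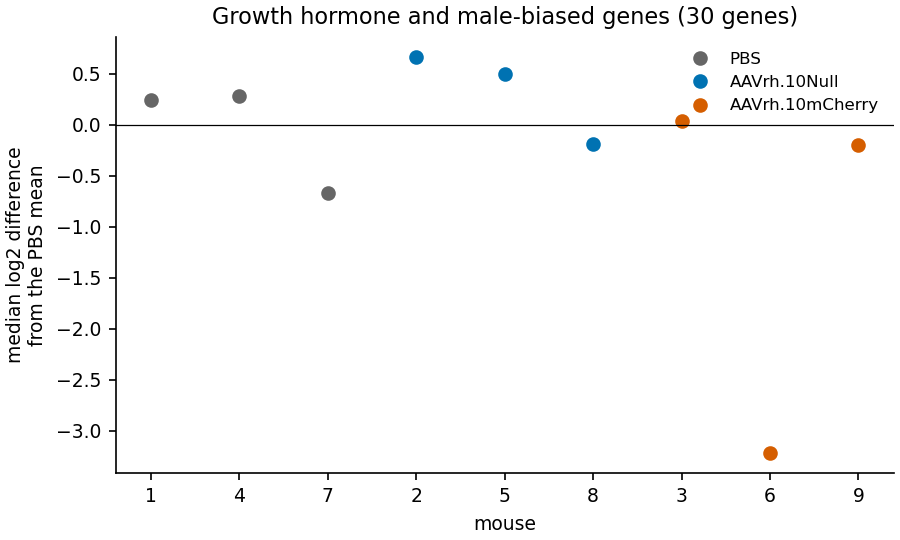
Median log2 difference from the PBS mean over 30 male-biased genes, with 1 point per mouse (n = 3 per group). Mouse 6 lies at −3.22 and the other 8 mice between −0.67 and 0.67.

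The frequency of non-hepatocyte classes was compared as a share of all retained barcodes. Stellate/fibroblast-like barcodes, which hold the vitamin A storing cells of the liver, made up 0.283 ± 0.0989% in PBS, 0.110 ± 0.0352% in AAVrh.10Null and 0.180 ± 0.0580% in AAVrh.10mCherry mice. The difference of both AAV groups from PBS was −0.138 percentage points (exact permutation p = 0.0357), and the smallest adjusted p over the 16 tests was 0.533. It was lost with named non-hepatocyte cells as denominator (exact p = 0.857), at no fewer than 100 or 500 genes per barcode (0.5 and 0.202), by edgeR (p = 0.103) and without any 1 of mice 2, 3, 4, 5, 7, 8 and 9. Kupffer/macrophage-like barcodes made up 0.442 ± 0.258%, 0.275 ± 0.0683% and 0.202 ± 0.156% (both AAV groups minus PBS −0.203, exact p = 0.131). T/NK-like barcodes made up 0.674 ± 0.743%, 0.204 ± 0.136% and 0.405 ± 0.115% (−0.369, exact p = 0.179), and endothelial-like barcodes 2.13 ± 2.26%, 0.856 ± 0.482% and 1.36 ± 0.802% (−1.02, exact p = 0.345). The T/NK difference turned upward without mouse 4 (0.0551), and the Kupffer difference with named non-hepatocyte cells as denominator (0.906) and at no fewer than 500 genes per barcode (0.277). The endothelial difference turned upward with the other denominator (3.09), at no fewer than 100 or 500 genes per barcode (0.548 and 2.21) and without mouse 7 (0.28), which was itself at 4.74%. With 3 mice against 3 the smallest possible exact p is 0.1, and the differences were −1.28 (exact p = 0.6), −0.166 (0.4), −0.470 (0.2) and −0.173 (0.1) for endothelial, Kupffer, T/NK and stellate classes in AAVrh.10Null minus PBS. For AAVrh.10mCherry minus PBS they were −0.772 (exact p = 0.9), −0.240 (0.3), −0.268 (0.8) and −0.103 (0.3), and for AAVrh.10mCherry minus AAVrh.10Null 0.503 (0.5), −0.0734 (0.5), 0.201 (0.3) and 0.0701 (0.2). Unnamed haemoglobin-led or mixed barcodes are part of the denominator, and their share differed between the mice as given above.

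The responses to the vectors were set side by side against PBS. No gene passed in both contrasts, at an adjusted p under 0.05 or under 0.1, and 0 would be expected. Over all barcodes the log2 changes correlated with r = 0.628 (rho = 0.619) and had a covariance of 0.181, and 73% of genes had the same sign. Simulated sets of unchanged groups, with the PBS mice redrawn too, gave r = 0.568 (0.550 to 0.587) and a covariance of 0.0992 (0.0945 to 0.104). In them 68.9% of genes had the same sign, since both contrasts share their controls. Genes were drawn independently there, without structure common to many genes. The simulation therefore cannot tell whether the values seen differ from those of unchanged groups. In hepatocyte-like sums r was 0.319 (rho = 0.269) with a covariance of 0.0736, below the simulated 0.608 (0.595 to 0.623) and 0.112 (0.108 to 0.118), and 58.4% of genes had the same sign against 70.3% in the simulation. In endothelial-like sums r was 0.434 (rho = 0.504) with a covariance of 0.147, against 0.521 (0.471 to 0.572) and 0.166 (0.143 to 0.189), and 69.7% of genes had the same sign against 67.3% in the simulation.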

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

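All tests in this part were chosen only after the results they address had been seen. Barcodes that the filter on cells left out were examined as data that no comparison uses: in the 202 left-out barcodes of mouse 6 (AAVrh.10mCherry), mCherry was at 1947 CPM (491 of 252214 UMIs), against 6364 CPM over the retained barcodes of that mouse. The 3051 left-out barcodes of mouse 7 (PBS) held 0 mCherry UMIs among 792560.

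Igkv3-12 transcripts stood at 124 to 248 CPM in the AAVrh.10Null mice and at 0 to 3.12 CPM in the other 6. RNA of B or plasma cells was tested by the constant segment Igkc, which a count at the end of a kappa transcript would take: there were 23.3 Igkv3-12 UMIs per Igkc UMI in the AAVrh.10Null mice (3311 against 142, exact interval 19.7 to 27.8), and this explanation was excluded. Carry-over from a library outside the group was excluded, since the lowest AAVrh.10Null mouse had 39.8 times the level of the highest other mouse. Carry-over among the AAVrh.10Null libraries was not tested. RNA of the vector itself, counted as this gene because of a similar sequence, could account for a feature of 1 treatment group found over hepatocyte-dominated barcodes. The variance-to-mean ratio was at most 1.27, but at 0.099 to 0.264 UMIs per barcode it would be near 1 for most spreads, and the vector sequence was not at hand, so the test could not decide. The gene also has close relatives in its family, so the assignment of reads to Igkv3-12 itself is uncertain. Ighv9-3 and Igkj1 were also seen only in the AAVrh.10Null mice, as given below, and this was not tested against any explanation.

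Mouse 6 (AAVrh.10mCherry) lacked much of the male liver program, with a median log2 difference of −3.22 over 30 male-biased genes and high Cyp2b9 and Sult2a7. A female animal under this label was excluded, since Ddx3y of the Y chromosome was at 104 CPM, within the 59.7 to 126 of the other mice, although Xist was at 1.66 CPM (at most 0.353 elsewhere). Without nuclear-led clusters 102.8% of the difference stayed. At 10% of mouse 6 barcodes they were too few to tell. An effect of this size shared by the AAVrh.10mCherry mice was excluded, since the larger change in mice 3 and 9 was −0.20. A cause particular to this animal, such as altered growth hormone signalling, was left untested.

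mCherry transcripts were found in 70.3% to 100% of the endothelial-like barcodes of the AAVrh.10mCherry mice. Free RNA of hepatocytes in the droplets fits this best, and may account for most of it, since the ratio of mCherry to Alb in these barcodes was 1.05 times that of hepatocyte-dominated barcodes in the median mouse. Doublets with hepatocytes were excluded as the general cause, since the median UMI count of endothelial-like barcodes was at most 60.6% of that expected of doublets. Expression of mCherry in endothelial cells at a level above hepatocytes was excluded, with a highest ratio of 1.21, and a lower level of own expression was not tested.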

How the results depend on the processing

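Alternatives added after the results had been seen are those named as such above. Contrasts are written Null-PBS, mCherry-PBS, AAV-PBS and mCherry-Null here, and values in parentheses after "from" are those of the original settings. No paired analysis was possible, since no replicate number occurs in 2 groups. The alternative without doublets was not run. Of 3342 values of named genes under other settings 3227 kept direction and side of the threshold, 33 were weaker, 53 stronger and 29 reversed, and of 2206 with a mouse left out 2149, 27, 13 and 17. Of 478 list results under other settings 183 kept both, 288 were weaker and 7 reversed, and of 983 with a mouse left out 772, 208 and 3. Of 112 share results under other settings 87 kept both, 5 were weaker and 20 reversed, and of 108 with a mouse left out 96, 7 and 5. mCherry in endothelial-like sums passed in each of the 20 settings that tested it in mCherry-PBS (adjusted p = 3.3e-15 to 0.00652) and in mCherry-Null (7.52e-13 to 0.00724). With at least 10 counts in at least 6 mice and with thinned sums it was not among the genes tested, and 0 genes were called. Igkv3-12 in hepatocyte-like sums passed in 19 of the 22 settings that tested it in mCherry-Null and in 16 of 22 in Null-PBS, and over all barcodes in 12 of 18 and 13 of 18. DESeq2 size factors in the edgeR fit left the calls of hepatocyte-like sums at 1, 0, 0 and 2, and over all barcodes mCherry-Null called 2 genes in place of 3, without Snhg20. The overlap of the contrasts with PBS stayed at 0 genes at a threshold of 0.1. At the depths of the 9 mice, 5.6% to 19.6% of simulated 2-fold changes were called.

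Camera with an estimated correlation and fry each called 0 lists throughout. These numbers stand in place of 6, 11, 10 and 10 in hepatocyte-like sums, 9, 8, 12 and 2 in endothelial-like sums and 5, 14, 9 and 17 over all barcodes, for Null-PBS, mCherry-PBS, AAV-PBS and mCherry-Null. With the DESeq2 Wald test, the genes called were, in hepatocyte-like sums, 0 in Null-PBS (from 1) and 6 in mCherry-Null (from 2), and, over all barcodes, 59 in Null-PBS (from 1), 2 in mCherry-PBS (from 0), 7 in AAV-PBS (from 0) and 0 in mCherry-Null (from 3). With limma-voom, the genes called were, in hepatocyte-like sums, 0 in Null-PBS (from 1) and 1 in mCherry-Null (from 2), and, over all barcodes, 0 in Null-PBS (from 1) and 0 in mCherry-Null (from 3). With no filter on low counts, the genes called were, in hepatocyte-like sums, 61 in Null-PBS (from 1), 32 in mCherry-PBS (from 0), 21 in AAV-PBS (from 0) and 402 in mCherry-Null (from 2), and, in endothelial-like sums, 2 in mCherry-Null (from 1), and, over all barcodes, 337 in Null-PBS (from 1), 101 in mCherry-PBS (from 0), 162 in AAV-PBS (from 0) and 158 in mCherry-Null (from 3). More genes were tested (24770 in place of 10293 hepatocyte-like and 26263 in place of 11308 over all barcodes), and beyond that the cause was not tested. With at least 10 counts in at least 6 mice, the genes called were, in hepatocyte-like sums, 0 in Null-PBS (from 1) and 0 in mCherry-Null (from 2), and, in endothelial-like sums, 0 in mCherry-PBS (from 1) and 0 in mCherry-Null (from 1), and, over all barcodes, 0 in Null-PBS (from 1) and 0 in mCherry-Null (from 3). By its construction this filter leaves out features seen in 1 group, such as mCherry and Igkv3-12, and for AI480526 and Snhg20 the cause was not tested. With only the mice of the 2 groups compared, the genes called were, in hepatocyte-like sums, 1 in mCherry-PBS (from 0) and 0 in mCherry-Null (from 2), and, over all barcodes, 1 in mCherry-Null (from 3). With sums thinned to the smallest total, the genes called were, in hepatocyte-like sums, 0 in Null-PBS (from 1), 1 in mCherry-PBS (from 0) and 1 in mCherry-Null (from 2), and, in endothelial-like sums, 0 in mCherry-PBS (from 1) and 0 in mCherry-Null (from 1). Opposite signs in hepatocyte-like sums were found for Psmb8 1.16 (from −0.59), Sdhd 0.09 (from −0.57) and mCherry 0.04 (from −0.86) in Null-PBS, Iigp1 −0.06 (from 0.19), Psmb8 1.41 (from −0.48), Pmvk 0.1 (from −0.56) and Elovl5 0.16 (from −0.85) in AAV-PBS and Mbl2 −0.13 (from 1.12), Acadm −1.84 (from 0.84), Sdhd −0.91 (from 0.58) and Atp5h −1.63 (from 0.58) in mCherry-Null. Opposite signs in endothelial-like sums were found for Cyp2e1 0.39 (from −1), mt-Nd4 −0.59 (from 1.36) and Maf −0.26 (from 0.82) in Null-PBS and Gstp1 0.11 (from −0.9), mt-Nd4 −0.55 (from 0.95), Maf −0.07 (from 0.7) and Bmp2 −0.53 (from 0.6) in AAV-PBS. Apart from the filters, the cause was not tested.

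With at least 100 genes per barcode, the genes called were, in hepatocyte-like sums, 0 in Null-PBS (from 1) and 1 in mCherry-Null (from 2), and, over all barcodes, 0 in mCherry-Null (from 3). Rps27 had the opposite sign at −0.31 (from 0.54) in hepatocyte-like sums of mCherry-PBS. Differences of shares in percentage points were, for endothelial-like barcodes 0.262 in Null-PBS, 0.833 in mCherry-PBS and 0.548 in AAV-PBS, and for stellate/fibroblast-like barcodes −0.053 in AAV-PBS. With at least 500 genes per barcode, the genes called were, in hepatocyte-like sums, 1 in mCherry-PBS (from 0), and, over all barcodes, 48 in Null-PBS (from 1). Differences of shares in percentage points were, for endothelial-like barcodes 2.46 in Null-PBS, 1.95 in mCherry-PBS, 2.21 in AAV-PBS and −0.51 in mCherry-Null, and for Kupffer/macrophage-like barcodes 0.77 in Null-PBS and 0.277 in AAV-PBS, and for T/NK-like barcodes −0.184 in mCherry-Null, and for stellate/fibroblast-like barcodes −0.734 in AAV-PBS and −0.17 in mCherry-Null. With at most 20 percent mitochondrial UMIs, the genes called were, in hepatocyte-like sums, 462 in Null-PBS (from 1), and, over all barcodes, 1 in mCherry-Null (from 3). C4b had the opposite sign at 0.09 (from −0.6) in hepatocyte-like sums of AAV-PBS. With Leiden resolution 0.5, the genes called were, in hepatocyte-like sums, 1 in mCherry-Null (from 2). With named non-hepatocyte barcodes as denominator, differences of shares in percentage points were, for endothelial-like barcodes 2.52 in Null-PBS, 3.65 in mCherry-PBS and 3.08 in AAV-PBS, and for Kupffer/macrophage-like barcodes 5.43 in Null-PBS and 0.906 in AAV-PBS, and for stellate/fibroblast-like barcodes −0.682 in AAV-PBS and −1.1 in mCherry-Null. edgeR on barcodes per class gave a log2 ratio of stellate/fibroblast-like shares of −0.91 in AAV-PBS (adjusted p = 0.208). The cause was not tested.

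With mice 6 and 7 left out, the genes called were, in hepatocyte-like sums, 1 in mCherry-Null (from 2), and, in endothelial-like sums, 2 in mCherry-Null (from 1), and, over all barcodes, 1 in mCherry-Null (from 3). Lists called were, in hepatocyte-like sums, 15 in Null-PBS (from 6), 19 in mCherry-PBS (from 11) and 18 in AAV-PBS (from 10), and, in endothelial-like sums, 3 in mCherry-PBS (from 8) and 1 in mCherry-Null (from 2), and, over all barcodes, 13 in Null-PBS (from 5) and 16 in AAV-PBS (from 9). Opposite signs in hepatocyte-like sums were found for Junb 0.01 (from −0.9) and Ier2 0.35 (from −0.81) in AAV-PBS. Igkv3-12 was at 0 (from 5.24) in mCherry-PBS. The list of ribosomal proteins (adjusted p = 0.0017, from 0.000567) turned direction in hepatocyte-like sums of mCherry-PBS. Differences of shares in percentage points were, for endothelial-like barcodes 0.0282 in Null-PBS, 0.089 in mCherry-PBS and 0.0525 in AAV-PBS, and for stellate/fibroblast-like barcodes −0.117 in AAV-PBS. With the 3 haemoglobin-led or mixed clusters added, the genes called were, in hepatocyte-like sums, 1 in mCherry-Null (from 2). Lists called were, in hepatocyte-like sums, 10 in Null-PBS (from 6). Rps27 had the opposite sign at −0.18 (from 0.54) in hepatocyte-like sums of mCherry-PBS. The list of ribosomal proteins (adjusted p = 0.0421, from 0.000567) turned direction in hepatocyte-like sums of mCherry-PBS. With all 4 unnamed clusters added, the lists called were, in hepatocyte-like sums, 10 in Null-PBS (from 6) and 16 in AAV-PBS (from 10). Rps27 had the opposite sign at −0.29 (from 0.54) in hepatocyte-like sums of mCherry-PBS. Rpl14 was at 0 (from 0.5) in mCherry-PBS. The list of ribosomal proteins (adjusted p = 0.00117, from 0.000567) turned direction in hepatocyte-like sums of mCherry-PBS. With the nuclear-led clusters left out, the genes called were, in hepatocyte-like sums, 1 in mCherry-PBS (from 0). Lists called were, in hepatocyte-like sums, 1 in Null-PBS (from 6) and 1 in AAV-PBS (from 10). Opposite signs in hepatocyte-like sums were found for H2-T23 0.06 (from −0.62), Cd74 0.16 (from −1) and H2-Aa 0.17 (from −1.16) in Null-PBS. Lists of MHC class II antigen presentation (adjusted p = 0.563, from 0.00748), apolipoproteins and lipoprotein assembly (adjusted p = 0.956, from 0.00719) and oxidative phosphorylation nuclear (adjusted p = 0.288, from 0.00098) turned direction in hepatocyte-like sums of Null-PBS. The list of oxidative phosphorylation nuclear (adjusted p = 0.0697, from 1.33e-05) turned direction in hepatocyte-like sums of mCherry-Null. With the endothelial-like sub-cluster of mouse 6 left out, the lists called were, in endothelial-like sums, 2 in mCherry-PBS (from 8), 7 in AAV-PBS (from 12) and 4 in mCherry-Null (from 2). The cause was not tested.

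With each mouse left out in turn, ranges are given for the results of which any value moved. Genes called ranged, in hepatocyte-like sums, from 0 to 2 in Null-PBS (from 1), from 0 to 1 in mCherry-PBS (from 0) and from 1 to 55 in mCherry-Null (from 2). They ranged, in endothelial-like sums, from 1 to 5 in mCherry-Null (from 1). They ranged, over all barcodes, from 0 to 8 in Null-PBS (from 1), from 0 to 4 in AAV-PBS (from 0) and from 0 to 5 in mCherry-Null (from 3). Lists called ranged, in hepatocyte-like sums, from 2 to 13 in Null-PBS (from 6), from 6 to 15 in AAV-PBS (from 10) and from 6 to 16 in mCherry-Null (from 10). They ranged, in endothelial-like sums, from 1 to 10 in Null-PBS (from 9), from 2 to 16 in mCherry-PBS (from 8), from 4 to 15 in AAV-PBS (from 12) and from 1 to 6 in mCherry-Null (from 2). They ranged, over all barcodes, from 5 to 17 in Null-PBS (from 5), from 8 to 20 in mCherry-PBS (from 14), from 2 to 18 in AAV-PBS (from 9) and from 10 to 17 in mCherry-Null (from 17). Log2 changes in hepatocyte-like sums that crossed or reached 0 ranged, in Null-PBS, mCherry −6.64 to 7.98 (from −0.86), and in mCherry-PBS, Sdf2l1 −1.3 to 0.01 (from −0.86), and in AAV-PBS, Nlrc5 −0.36 to 0.96 (from 0.42), Sdf2l1 −0.83 to 0.31 (from −0.56), Ier2 −1.32 to 0.26 (from −0.81) and Igkc −2.7 to 0 (from −1.74). Log2 changes in endothelial-like sums that crossed or reached 0 ranged, in Null-PBS, Thrsp −1.43 to 0.38 (from −0.91), Apob −0.89 to 0.11 (from −0.55) and mCherry −2.89 to 0 (from −2.24), and in mCherry-PBS, Thrsp −1.57 to 0.11 (from −1.18), and in AAV-PBS, Thrsp −1.43 to 0.24 (from −1.04), and in mCherry-Null, Mup18 −3.6 to 0.84 (from −2.73) and Mup17 −2.72 to 0.19 (from −1.9). Log2 changes over all barcodes that crossed or reached 0 ranged, in Null-PBS, mCherry −6.86 to 8.31 (from −0.68), and in mCherry-PBS, Igkv3-12 0 to 5.9 (from 5.24) and Snhg20 −0.18 to 0.22 (from 0.05). Lists that turned direction were ribosomal proteins in hepatocyte-like sums of mCherry-PBS (adjusted p = 2.07e-07 to 0.551, from 0.000567, turned without mouse 6), endothelial activation and capillarization in endothelial-like sums of AAV-PBS (adjusted p = 0.00562 to 0.92, from 0.0344, turned without mouse 1) and heat shock and dissociation stress over all barcodes of mCherry-PBS (adjusted p = 3.45e-06 to 0.408, from 0.00981, turned without mouse 4). Differences of shares ranged, for endothelial-like barcodes −2.01 to 0.0282 in Null-PBS (from −1.28), −1.51 to 0.531 in mCherry-PBS (from −0.772) and −1.76 to 0.28 in AAV-PBS (from −1.02), and for T/NK-like barcodes −0.538 to 0.156 in mCherry-PBS (from −0.268) and −0.638 to 0.0551 in AAV-PBS (from −0.369), and for stellate/fibroblast-like barcodes −0.193 to −0.0976 in AAV-PBS (from −0.138), in percentage points. Fewer mice per group were tested here, and beyond that the cause was not tested.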

Other observations

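All tests of hypotheses in this part were chosen only after the results they address had been seen. Further genes were measured at higher levels in mouse 6 than in most other mice. Cyp17a1, which makes androgen precursors, was at 62.2 CPM (at most 5.36 elsewhere), and Cyp4a14, an omega-hydroxylase induced by PPARA, at 405 (at most 114 elsewhere). Hamp2, of the hepcidin family, was at 475, with 447 in mouse 7. In mouse 7 (PBS) Igkc and Igha, at the levels given above, rested on 111 and 62 of 290531 retained UMIs.

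The origin of the mCherry UMIs of mice 1 and 5, index hopping or carry-over included, was not tested.

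Other immunoglobulin segments were seen in the AAVrh.10Null mice. Ighv9-3 had 5, 53 and 47 UMIs in mice 2, 5 and 8, and 104 of these 105 lay in hepatocyte-dominated barcodes, as did 3291 of the 3311 UMIs of Igkv3-12. Igkj1 had 23 UMIs, Igkv3-3 14, Igkv3-7 6 and Ighv9-1 5, all in hepatocyte-dominated barcodes. These segments and Ighv9-3 had 0 UMIs in the PBS and AAVrh.10mCherry mice. Igkj5 had 9 UMIs in AAVrh.10Null and 1 in PBS mice, and Igkv6-32 had 5, all in mouse 7 (PBS). Igkc had 142 UMIs in AAVrh.10Null, 271 in PBS and 80 in AAVrh.10mCherry mice. The zonation markers Cyp2e1, pericentral, and Cyp2f2, periportal, had variance-to-mean ratios of 1.36 to 2.95 and 1.08 to 1.44 over hepatocyte-dominated barcodes. Once depth was taken out, they correlated with r between −0.0993 and 0.0259 within mice. In the reference annotation, Igkv3-12 lies on chromosome 6 in the same orientation as Igkc, and AI480526 and Snhg20 are long intergenic RNAs of chromosomes 5 and 11.

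Exchanging the group labels among the mice tested whether the counts of genes and lists exceed those of arbitrary groupings. A real count of 0 genes is reached by every split, so it says nothing about chance. This holds for both AAV groups against PBS over all barcodes (84 of 84 splits, highest other 12), in hepatocyte-like sums (84 of 84, highest other 594) and in endothelial-like sums (56 of 56, highest other 5). At least the real number of lists was called by 69 splits over all barcodes (9 real, highest other 24), 53 in hepatocyte-like sums (10 real, highest other 19) and 13 in endothelial-like sums (12 real, highest other 15). The split of the hepatocyte-like sums with 594 genes sets mice 2, 7 and 8 against the rest, and another with 209 genes sets mice 2, 4 and 8 against the rest, which points to a structure of the samples.

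For 3 mice against 3 the 10 splits are too few for a share under 0.05, and where 0 genes are real all 10 reach that number. Over all barcodes, AAVrh.10Null minus PBS called 1 gene (reached in 2 splits, highest other 2) and 5 lists (10 splits, highest other 22). AAVrh.10mCherry minus PBS called 0 genes (10 splits, highest other 1) and 14 lists (7 splits, highest other 22). AAVrh.10mCherry minus AAVrh.10Null called 3 genes (1 split, highest other 0) and 17 lists (2 splits, highest other 17). In hepatocyte-like sums the same contrasts called 1 gene (3 splits, highest other 8) and 6 lists (9, highest other 12), 0 genes (10, highest other 1) and 11 lists (6, highest other 17), and 2 genes (1, highest other 0) and 10 lists (6, highest other 16). In endothelial-like sums AAVrh.10mCherry minus PBS called 1 gene (1, highest other 0) and 8 lists (5, highest other 15).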
